A study of Mus musculus with 12 samples.

How the data were processed

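RNA labelled as from CTLL-2 cells, a mouse cytotoxic T cell line that depends on interleukin 2 (IL-2), was measured on 12 Affymetrix Mouse Genome 430 2.0 arrays, 4 in each of 3 groups. Per the labels' protocols, cells grown in 50 U/mL IL-2 were starved of it for 14 h and then given cycloheximide, an inhibitor of translation, at 20 µg/mL. Per the labels, the groups received cycloheximide for 30 min, cycloheximide for 4.5 h, or cycloheximide for 30 min followed by 100 U/mL IL-2 for 4 h with cycloheximide present. A group without cycloheximide that the series' text mentions was not analysed here. Total RNA was isolated on RNeasy columns and labelled as biotinylated cRNA, per the labels' protocols.

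The authors' deposited table holds 1 linear intensity signal per probe set and array, made with GCOS 1.3 per the submitters' processing notes. The deposited signals of each array had the same trimmed mean of 500 after leaving out the lowest and highest 2% of probe sets, so the arrays had been scaled before deposit. The background correction and the algorithm that summarised the probes are not given in the sources used here. The scanner's experiment-information files, deposited by the authors and read per the file headers, were used only to number the days on which arrays were scanned. The labels give replicate numbers and do not say that replicates were separate cultures, so p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision.

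Signals were analysed as log2(signal + 16) with no further normalization, so differences of dim probe sets are understated. Of 45101 probe sets, 64 controls were left out, and of the remaining 45037 the 27022 with a mean log2 value at or above the 40th percentile were tested, which corresponds to a signal of 34.9. Gene symbols came from the platform's probe table, updated through gene identifiers. Among the probe sets that are not controls, 34945 had 1 symbol, 932 had several and 9160 had none in that table. Where a gene had several probe sets the brightest stood for it, which gave 12855 genes. Of 5853 genes with more than 1 probe set, probe sets of 1 gene were called in opposite directions for 17 genes with IL-2 at matched time, 32 genes over time and 6 genes in the remaining comparison.

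One linear model with 3 groups was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), and p-values were adjusted by Benjamini-Hochberg over the probe sets tested. A probe set was called at an adjusted p under 0.05 with at least a 2-fold difference. Of 26 gene lists, 24 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01, adjusted over 72 tests. Camera with an estimated correlation and fry were run beside it. Members were also counted with the p-value adjusted over the list alone. These groups, tests, lists, thresholds and alternatives, and the rule for named genes, were set before the data were examined.

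The rule named the 12 largest rises and 12 largest falls among called genes whose arrays did not overlap between the groups (5 and 5 for IL-2 against 30 min), leaving out clone and locus names. It also named up to 4 members of each list by p-value in each comparison, and 9 fixed genes: Cish, Socs1, Socs2, Socs3, Pim1, Il2ra, Bcl2, Myc and Ccnd2. The text gives 98 of these genes. The library labelled IL-2 plus cycloheximide replicate 3 did not carry T cell transcripts. A fit of the other 11 arrays, with 3 of them in the IL-2 group, was therefore added after the data were seen, and the rule was applied to it as well. Counts are given from both fits, and gene and list values are from the 11 arrays unless stated otherwise.

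The alternatives were quantile normalization, centring on each array's median or on ribosomal protein genes, pseudocounts of 1 and 64, no filter or a 60th percentile filter, eBayes with trend and robust settings, array weights and only the 2 groups compared. Others were the replicate number as a block, limma's treat against a 2-fold change, no fold threshold, an adjusted p under 0.01, leaving out probe sets that can cross-hybridize, the mean over a gene's probe sets, the scan day as a block and leaving out each array in turn. Comparisons of lists of calls that shared arrays were set beside 20 simulations of unchanged groups, which hold no effects, and beside independent lists, which leave out the shared arrays. Figures were drawn with python 3.11.15.

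The fit was tested on simulated data with the spread of these arrays, for IL-2 at matched time over 27022 probe sets with 50 changed at each size. Recovery was scored at an adjusted p under 0.05 in the right direction, without the 2-fold threshold, so the shares are not those of the calling rule. The simulated data also held fewer changed probe sets than were called in the real data, which affects the adjustment. With 12 arrays 0% of 1.5-fold, 12% of 2-fold, 24% of 3-fold and 40% of 4-fold changes were recovered, and 1 of 26822 unchanged probe sets passed. With 11 arrays 8%, 32%, 64% and 68% were recovered, and 9 of 26822 passed.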

Results

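Gene expression was measured in RNA labelled as from CTLL-2 cells, a mouse cytotoxic T cell line that needs the cytokine IL-2 to grow and survive. Per the labels, cells were starved of IL-2 for 14 h and then treated with cycloheximide, which blocks translation. There were 4 arrays labelled as 30 min of cycloheximide, 4 as 4.5 h of cycloheximide, and 4 as cells given cycloheximide for 30 min and then IL-2 for 4 h with cycloheximide present. Array medians ran from 57.7 to 78.3 signal units, and 22.1% to 24.0% of probe sets on each array exceeded a signal of 500. Arrays were scanned on 3 days. The first day held 3 arrays of the IL-2 group and 3 of the 30 min group, the second held 1 of each, and the third held all 4 arrays of the 4.5 h group.

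The library labelled IL-2 plus cycloheximide replicate 3 lacked T cell transcripts. Its signals were 27.0 for Cd3e, a chain of the T cell receptor complex, 8.40 for Ptprc, the leukocyte surface phosphatase CD45, 4.80 for Gzmb, a granule protease, and 106 for Prf1, the pore-forming protein perforin. The lowest signals of these genes on any other array were 3614, 16201, 34212 and 22233. It carried the muscle transcripts Myod1, a muscle lineage transcription factor, at 19045 and Acta1, skeletal muscle actin, at 40277, against at most 84.6 and 262 on the other 11 arrays. Of 11 muscle genes read first 10 were higher on it than on every other array, the exception being Ckm, muscle creatine kinase, at 1690 against up to 4563. The mean log2 value of T cell identity genes was 5.42 on it, against 12.5 ± 0.07 (SD, n = 3) on the other IL-2 arrays, 12.7 ± 0.06 (SD, n = 4) at 30 min and 12.5 ± 0.06 (SD, n = 4) at 4.5 h. Its correlation with the other arrays was 0.732 to 0.756 across probe sets, which are not independent replicates. The lowest correlation among the other 11 arrays, within or between groups, was 0.914. These marker genes were chosen after their values were seen.

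**Figure D1:**
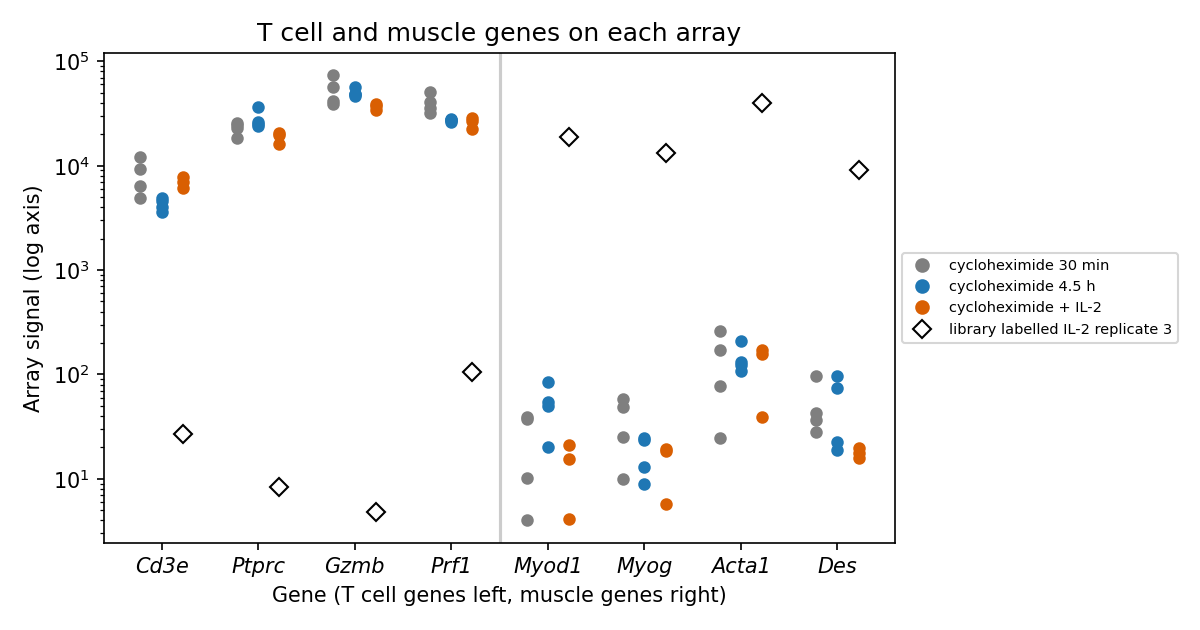
Array signal on a log axis for T cell genes (left) and muscle genes (right), with 1 point per array coloured by group and an open diamond for the library labelled IL-2 plus cycloheximide replicate 3. That library lies below every other array for Cd3e, Ptprc, Gzmb and Prf1 and above every other array for Myod1 and Acta1.

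IL-2 at matched time compared cells with and without the cytokine after 4.5 h in cycloheximide. With 11 arrays camera called the lists of STAT5-driven, ERK feedback, immediate early and cytokine genes up and those of DNA replication, mitosis and ribosomal proteins down. With an estimated correlation 0 of these 7 held. Csn2, which encodes the milk protein beta-casein and is a classical STAT5 target, stood at 17414 ± 1222 (SD, n = 3) with IL-2 and 1576 ± 660 (SD, n = 4) without, a log2 difference of 3.53 ± 0.25 (SE, adjusted p = 2.76e-05). Myc, a transcription factor that drives growth, stood at 1803 ± 379 (SD, n = 3) against 167 ± 59.2 (SD, n = 4), a log2 difference of 3.34 ± 0.29 (SE, adjusted p = 5.89e-05). With 12 arrays 1196 of 27022 probe sets were called, 505 higher and 691 lower with IL-2, representing 205 and 363 genes. Without the library labelled IL-2 plus cycloheximide replicate 3 the count was 3272, 1783 higher and 1489 lower, representing 640 and 763 genes. Of the 1196, 1051 (87.9%) were called in the same direction in both fits with 0 opposite.

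The largest rises were in Cysltr1, a receptor for cysteinyl leukotrienes, by 5.72 ± 0.51 (log2, SE, adjusted p = 7.07e-05), Espn, an actin-bundling protein, by 4.2 ± 0.21 (adjusted p = 5.77e-06), and Igfals, which binds insulin-like growth factor complexes, by 4.18 ± 0.34 (adjusted p = 4.79e-05). Fos, a subunit of the AP-1 transcription factor, rose by 3.94 ± 0.57 (adjusted p = 8.47e-04), Fgl2 by 3.82 ± 0.31 and Hbegf, an EGF receptor ligand, by 3.32 ± 0.33. As the rule for naming them required, for each of these genes all 3 IL-2 arrays lay above all 4 arrays without IL-2. Fitted with 12 arrays, Myc rose by 3.36 ± 0.28, Dusp1 by 3.72 ± 0.31, Espn by 3.65 ± 0.45, Cited2 by 3.15 ± 0.29 and Fosl1, another AP-1 subunit, by 3.93 ± 0.71. All of these took in the library labelled IL-2 plus cycloheximide replicate 3, where the signals were 1878 for Myc, 6292 for Dusp1, 81 for Espn, 17642 for Cited2 and 4829 for Fosl1. For Fosl1 that stood against 507 ± 76.9 (SD, n = 3) on the other IL-2 arrays and 45.9 ± 17.6 (SD, n = 4) without IL-2.

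Of 20 STAT5-driven cytokine response genes, 11 rose and 0 fell with IL-2 over all genes tested, and 11 and 0 adjusted over the list alone, with a median log2 difference of 1.22. The list was shifted up by camera (adjusted p = 8.49e-10), and the adjusted p with an estimated correlation was 0.157. Cish, a feedback inhibitor of cytokine receptors, rose by 2.07 ± 0.33 (SE, adjusted p = 0.00145), to 9592 ± 557 (SD, n = 3) from 2553 ± 1611 (SD, n = 4). Its relatives Socs1, Socs3 and Socs2 rose by 2.32 ± 0.28, 1.73 ± 0.22 and 1.13 ± 0.14. Lta, the cytokine lymphotoxin alpha, rose by 2.32 ± 0.13, Osm, the cytokine oncostatin M, by 2.74 ± 0.25, and Il2ra, the alpha chain of the IL-2 receptor, by 2.12 ± 0.19. Pim1, a survival kinase, differed by 0.41 ± 0.23 (adjusted p = 0.210) and Ccnd2, cyclin D2, by 0.41 ± 0.16 (adjusted p = 0.0723), and neither was called, although both were with centring on ribosomal protein genes (1.14 each). In the 12-array fit 2 of the 20 were called, the list median was 0.47 (adjusted p = 0.0110, and 0.752 as the adjusted p with an estimated correlation), and the list was not called without IL-2 plus cycloheximide replicate 1 (0.32), 2 (0.34) or 4 (0.34). Ribosomal protein centring also ended that call (median 1.07, adjusted p = 0.205).

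**Figure D2:**
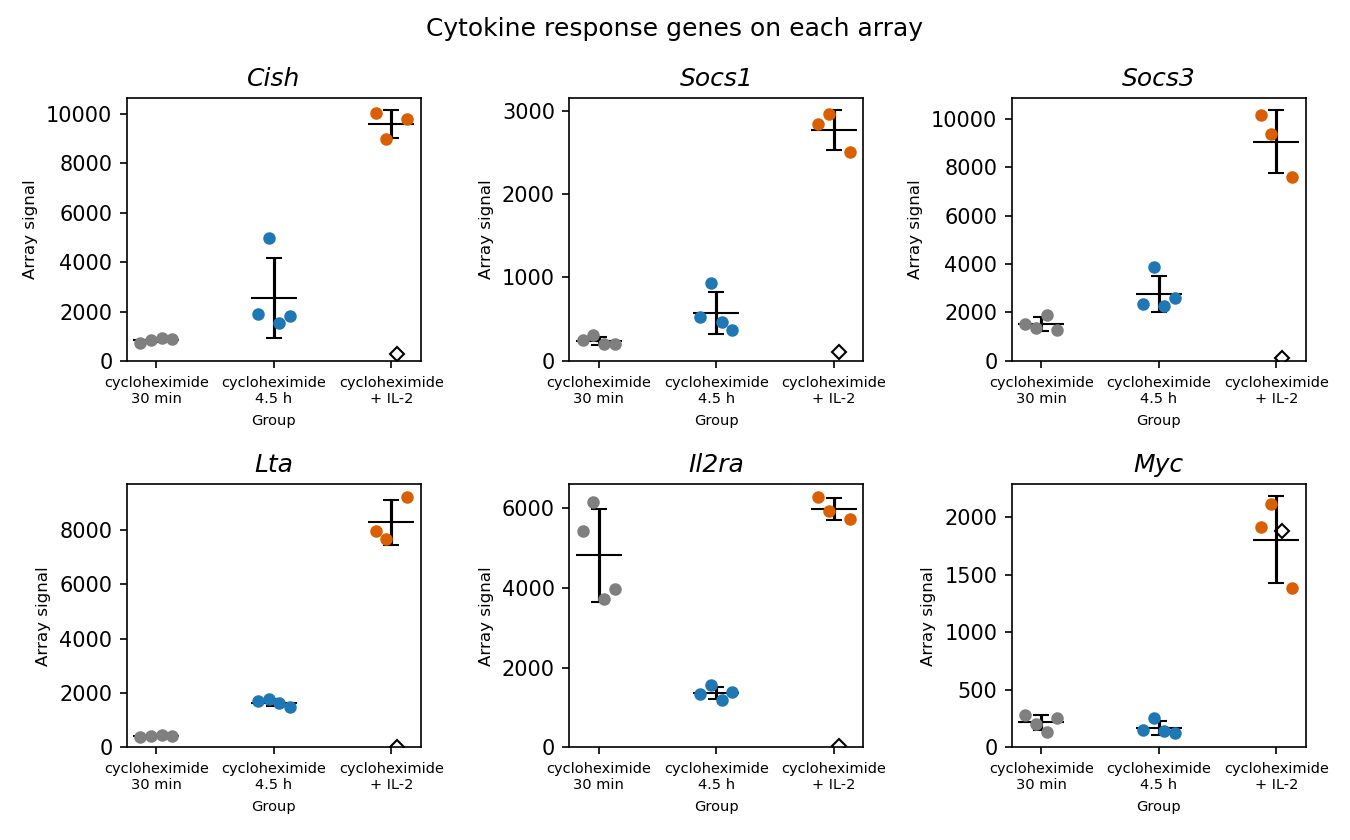
Array signal of cytokine response genes in each group, with 1 point per array, an open diamond for the library labelled IL-2 plus cycloheximide replicate 3, and bars for the mean and SD of the other arrays. For Cish the 3 T cell arrays with IL-2 lie between 8965 and 10029, above the highest 4.5 h array without IL-2 at 4960.

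Of 18 ERK pathway feedback genes 11 rose and 0 fell, and 11 and 0 adjusted over the list alone (median 1.45, camera adjusted p = 5.94e-09, and adjusted p = 0.0580 with an estimated correlation). They included the phosphatase Dusp4 at 2.71 ± 0.18 (SE, adjusted p = 1.90e-05), Spry4 at 2.65 ± 0.25 and Spred1 at 2.91 ± 0.17. The list holds transcription factor genes such as Etv5 and Myc beside genes that restrain growth factor signalling. It shares members with the STAT5 and immediate early lists. With all 12 arrays 8 of 18 rose (median 1.22, adjusted p = 1.64e-12), and the adjusted p with an estimated correlation was 0.00404. Of 34 immediate early genes, 13 rose and 1 fell by either adjustment (median 0.54, adjusted p = 3.61e-06, and adjusted p = 0.149 with an estimated correlation). Among them were Dusp1, a MAP kinase phosphatase, at 3.54 ± 0.29, Atf3, a stress-induced transcription factor, at 2.32 ± 0.14, and Gadd45b at 1.48 ± 0.13, which was not called as a mean over its probe sets (0.51). Of 18 cytokine and chemokine genes 5 rose and 1 fell, or 6 and 1 adjusted over the list alone (median 0.48, adjusted p = 0.0213, and adjusted p = 0.157 with an estimated correlation). Ifng, interferon gamma, rose by 3.19 ± 0.35 and the chemokine Ccl5 fell by 1.82. The cytokine list was not called with the mean over probe sets (adjusted p = 0.0502) or with ribosomal protein centring (adjusted p = 0.104).

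Bcl2 and Bcl2l1, which protect from apoptosis, rose by 1.63 ± 0.23 (SE, adjusted p = 7.63e-04) and 1.3 ± 0.23 (adjusted p = 0.00216), and were the 2 called of 4 anti-apoptotic BCL2 family genes, too few to test as a list. Bbc3 and Bmf, BH3-only genes that promote apoptosis, fell (log2 differences −1.86 and −1.82, adjusted p = 0.00229 and 6.57e-05), and the 10 pro-apoptotic genes were not called as a list (median −0.27, or 0.45 with ribosomal protein centring, adjusted p = 0.776). Hk2, which phosphorylates glucose, rose by 1.82 ± 0.17, and Slc2a1, the glucose transporter GLUT1, by 1.06 ± 0.18 (0.98 and not called without the 4.5 h replicate 1). Of the 19 genes of glucose uptake and glycolysis 3 rose and 0 fell by either adjustment, and the list was not called (adjusted p = 0.685, and adjusted p = 0.842 with an estimated correlation). Its median was −0.24 and its mean 0.06. The median turned to 0.045 with quantile normalization and 0.48 with ribosomal protein centring. Stard4 and Msmo1 of cholesterol transport and synthesis rose by 1.57 ± 0.18 and 1.49 ± 0.25. Of 20 cholesterol genes 4 rose and 0 fell by either adjustment, and the list was not called (median 0.04, adjusted p = 0.236, and adjusted p = 0.677 with an estimated correlation). That median turned to −0.039 with the mean over probe sets or without cross-hybridizing probe sets, and to −0.015 without IL-2 plus cycloheximide replicate 2. Irf9 and Stat2, subunits of the interferon-activated factor ISGF3, rose by 2.05 ± 0.24 and 1.44 ± 0.15. Of 25 interferon response genes 3 rose and 2 fell, or 3 and 3 adjusted over the list alone, and the list was not called (median −0.16, or 0.56 with ribosomal protein centring, adjusted p = 0.583, and adjusted p = 0.777 with an estimated correlation). Cd28, a T cell costimulatory receptor, rose by 2.51 ± 0.29. The FOXO-related gene Cited2 rose by 2.82 ± 0.14, while Mxd4, a Myc antagonist, Ccng2, a cyclin linked to cell cycle arrest, and the repressor Bcl6 fell (−2.41, −1.15 and −1.35). Of the 28 FOXO and quiescence genes 1 rose and 6 fell by either adjustment (median −0.47, adjusted p = 0.0589, and adjusted p = 0.246 with an estimated correlation). With ribosomal protein centring the list was called lower than other genes (adjusted p = 0.00633) although its median turned to 0.26. It was also called with no filter (adjusted p = 0.0256), a pseudocount of 64 (0.0480) or no cross-hybridizing probe sets (0.0471), and without IL-2 plus cycloheximide replicate 1 (adjusted p = 0.0387) or 2 (0.0428) or the 4.5 h replicate 3 (0.0421).

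Of 34 genes of the G1/S transition and DNA replication, 20 fell and 3 rose with IL-2, or 21 and 3 adjusted over the list alone (median −1.43, adjusted p = 1.78e-06, and adjusted p = 0.106 with an estimated correlation). Mcm5 and Mcm3, subunits of the replicative helicase, fell (log2 differences −3.92 and −2.62, adjusted p = 7.55e-06 and 1.37e-05), as did Cdt1, which loads that helicase (−2.95), Tk1, thymidine kinase (−2.86), and Gins2 (−2.76). Outside the list Rnf207 (−4.09), Wdfy4 (−3.46), Cks1b, a cyclin-dependent kinase subunit (−2.86), and Pclaf, which binds PCNA (−2.76), fell. For the falls of Rnf207, Wdfy4, Mcm5, Cdt1, Tk1, Cks1b, Gins2 and Pclaf all 3 IL-2 arrays lay below all 4 arrays without IL-2, as the rule for naming the largest falls required. With 12 arrays the differences were −3.83 for Rnf207 and −3.16 for Mcm5, whose signals on the library labelled IL-2 plus cycloheximide replicate 3 were 70.7 and 2064. That call of Mcm5 was lost when only the 2 groups were compared (adjusted p = 0.0577). Of 27 genes of G2/M and mitosis 12 fell and 0 rose, or 13 and 0 adjusted over the list alone (median −0.98, adjusted p = 1.96e-07, and adjusted p = 0.360 with an estimated correlation). Mad2l1, a spindle checkpoint gene (−1.93), Birc5, survivin (−1.75), and Ccnb2, cyclin B2 (−1.59), were among them. Of 44 cytosolic ribosomal protein genes 5 fell and 0 rose by either adjustment (median −0.78, adjusted p = 4.74e-09, and adjusted p = 0.368 with an estimated correlation), among them Rpl27a (−2.59), and with quantile normalization the median was −0.09 and the list was not called (adjusted p = 0.154, and 0.254 with 12 arrays).

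Cell identity lists were not called with IL-2 in the 11-array fit. The median was −0.37 for 19 cytotoxic effector genes (adjusted p = 0.302) and −0.30 for 13 T cell identity genes (adjusted p = 0.387), and both turned positive with quantile normalization (0.10 and 0.26) and ribosomal protein centring (0.35 and 0.42). With the library labelled IL-2 plus cycloheximide replicate 3 included the medians were −2.46 and −2.11 (adjusted p = 0.0568 each). Both were then called with median centring (0.0253 each), no filter (0.0439 each), the replicate block (0.0432 and 0.0468) and ribosomal protein centring (1.41e-05 and 1.71e-05), and the cytotoxic list with the mean over probe sets (0.0303). Both were also called without IL-2 plus cycloheximide replicate 1, 2 or 4 (adjusted p from 0.00996 to 0.0151). Markers of B cells, myeloid cells and fibroblasts had adjusted p-values of 0.623, 0.777 and 0.882, and erythroid markers, with 3 genes tested, were not tested as a list. Across the 24 lists tested, 7 were called in each fit, 4 up and 3 down, and with an estimated correlation 1 was called with 12 arrays and 0 with 11. The fits differed for the cytokine list, not called with 12 arrays (median −0.0092, adjusted p = 0.819). They differed too for the ATF4 list, called up with 12 arrays (median 0.15, or −0.18 with array weights, adjusted p = 0.0289, and adjusted p = 0.766 with an estimated correlation) and not with 11 (−0.28, adjusted p = 0.383) or with quantile normalization (adjusted p = 0.0691). The 17 lists not called with 11 arrays had adjusted p-values from 0.0589 to 0.882.

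The 4.5 h arrays were all scanned on a day of their own, so for IL-2 at matched time the scan day and the group cannot be told apart. On them the 3′ minus 5′ log2 difference of Actb was 0.56 ± 0.17 (SD, n = 4, lowest 0.418), against 0.29 ± 0.04 (SD, n = 4, highest 0.329) at 30 min and 0.25 ± 0.03 (SD, n = 3, highest 0.268) with IL-2. That of Gapdh was −0.08 ± 0.08 (SD, n = 4), against −0.21 ± 0.09 (SD, n = 4) and −0.22 ± 0.05 (SD, n = 3). The share of calls that were higher was 42.2% with 12 arrays and 54.5% with 11, but 96.2% and 96.7% with ribosomal protein centring, which moved the median of all probe sets by 0.61 and 0.72 (log2) and ended the calls of Bcl6, Ccng2, Ccl5 and Ccnb2. The mean over probe sets also ended those of Socs2 (0.83), Bcl6 (−0.75) and Ccng2 (−0.94), and a pseudocount of 64 that of Ccl5 (−0.95). In the 12-array fit the count fell to 565, 759, 536 and 548 without the 4.5 h replicates 1, 2, 3 and 4.

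Over 4 further hours in cycloheximide without IL-2, the comparison of 4.5 h with 30 min showed the course of transcripts in starved cells. With 11 arrays camera called the lists of ribosome biogenesis, DNA replication, NF-kappaB feedback, decay substrate and ribosomal protein genes up and those of unfolded protein response, ATF4 and glucose genes down. Of these 8 the ribosome biogenesis list alone held with an estimated correlation. Rnf207 rose to 706 ± 128 from 41.9 ± 18 (SD, n = 4 each), a log2 difference of 3.69 ± 0.36 (SE, adjusted p = 8.55e-05), and stood at 30.6 ± 22.2 (SD, n = 3) with IL-2. Csn2 fell to 1576 ± 660 from 16255 ± 2030 (SD, n = 4 each), and Csn3, kappa-casein, to 1075 ± 77 from 11111 ± 1015 (SD, n = 4 each), with log2 differences of −3.42 and −3.35 (adjusted p = 1.49e-05 and 4.73e-06). With 12 arrays 1885 probe sets were called, 910 higher and 975 lower, representing 462 and 322 genes. In the 11-array fit 3570 were called, 1758 higher and 1812 lower, representing 932 and 608 genes, and all 1885 (100%) were among them in the same direction. The direction could not differ, since both groups hold the same arrays in each fit and only the estimate of the spread changes.

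Other large rises at 4.5 h were in Jpt2, by 3.48 ± 0.45 (SE, adjusted p = 3.44e-04), Tha1, a threonine aldolase, by 3.37 ± 0.18 (adjusted p = 1.10e-05), Cd7, a T cell surface protein, by 3.23 ± 0.80 (adjusted p = 0.0110), Pcdh9, a protocadherin, by 3.18 ± 0.45, Icam2, an adhesion molecule, by 2.95 ± 0.64, and Fbxo31 by 2.94 ± 0.19. Other large falls were in Ankrd37, a hypoxia-inducible gene (−3.61, adjusted p = 1.10e-05), Chac1, which degrades glutathione (−3.52), Fbxo32, a FOXO-induced ubiquitin ligase subunit (−3.18), Espn (−3.16), Itgb3, integrin beta 3 (−3.07), and Synj2 (−3.05). Cysltr1 and Cd28 fell too (−2.83 and −2.79), and Il2ra fell by 1.78. For the largest rises and falls the 4 arrays of one group did not overlap the 4 of the other, as the rule for naming them required.

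Of 40 genes of Myc and ribosome biogenesis, 13 rose and 0 fell by either adjustment (median 0.68, adjusted p = 3.16e-09), and the call held with an estimated correlation (adjusted p = 0.0203). They included Dkc1, Rrs1 and Polr1b, a subunit of RNA polymerase I, at 2.16 ± 0.19, 1.72 ± 0.17 and 1.48 ± 0.16 (SE). Of 34 G1/S and replication genes 15 rose and 0 fell by either adjustment (median 0.95, adjusted p = 1.95e-04, and adjusted p = 0.157 with an estimated correlation), with Mcm5 at 2.84 ± 0.20, Mcm3 at 2.55 ± 0.16 and Mcm4 at 1.56 ± 0.16. Of 17 NF-kappaB feedback and target genes 8 rose and 0 fell by either adjustment (median 0.82, adjusted p = 1.35e-05, and adjusted p = 0.157 with an estimated correlation). Among these Bcl3, Relb and the inhibitors Nfkbie and Nfkbia rose by 2.00 ± 0.17, 1.96 ± 0.19, 1.77 ± 0.26 and 1.47 ± 0.17. Of 26 transcripts known as substrates of nonsense-mediated decay, a process that needs translation, 8 rose and 0 fell by either adjustment (median 0.59, adjusted p = 9.77e-05, and adjusted p = 0.157 with an estimated correlation). Srsf3, a splicing factor, rose by 1.25 ± 0.16. Rbm39, another, rose by 1.14 ± 0.12 at its brightest probe set but had a log2 difference of −0.51 as a mean over its probe sets (adjusted p = 0.0268). The ribosomal protein list was shifted up (1 of 44 rose, median 0.32, adjusted p = 0.0106, and adjusted p = 0.777 with an estimated correlation). That call was lost with quantile normalization (0.08, adjusted p = 0.473), without cross-hybridizing probe sets (adjusted p = 0.0501), and without the 30 min replicate 4 (0.22) or the 4.5 h replicate 2 (0.16).

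Of 22 unfolded protein response genes 6 fell and 1 rose by either adjustment (median −0.75, adjusted p = 8.85e-05, and adjusted p = 0.164 with an estimated correlation). Dnajb9 and Pdia4, which help proteins fold in the endoplasmic reticulum, fell (−2.35 and −1.75), while Ddit3, the stress-induced factor CHOP, rose by 1.31 ± 0.18 (SE), and was not called as a mean over its probe sets (0.43). Of 32 ATF4 and amino acid response genes 7 fell and 1 rose by either adjustment (median −0.28, adjusted p = 0.00414, and adjusted p = 0.350 with an estimated correlation). The amino acid transporters Slc7a1, Slc7a3 and Slc38a2 fell (−2.52, −1.98 and −1.62), and Slc38a2 was not called as a mean over its probe sets (−0.84). Of 19 genes of glucose uptake and glycolysis 2 fell and 0 rose by either adjustment (median −0.35, adjusted p = 0.00323, and adjusted p = 0.157 with an estimated correlation), namely Slc2a1 (−2.42) and the aldolase Aldoc (−2.39). Of 20 cholesterol genes 6 fell and 2 rose (median −0.10, adjusted p = 0.132), and the synthesis enzymes Sqle and Cyp51 fell (−2.37 and −1.65) while Mvd rose by 1.63 ± 0.12. With 12 arrays the cholesterol list was called down (adjusted p = 0.0494, and adjusted p = 0.729 with an estimated correlation), but not without the 30 min replicates 1 (0.104) or 3 (0.0646) or the 4.5 h replicates 1 (0.0599) or 4 (0.0597), or under 6 other alternatives (0.0525 to 0.0968). The p53 target list was called down with 12 arrays (median −0.33, adjusted p = 0.0472, and adjusted p = 0.577 with an estimated correlation) and not with 11 (adjusted p = 0.179). That call was also lost without the 30 min replicates 1 (0.0768) or 2 (0.0565) or the 4.5 h replicate 2 (0.0808), and under 5 other alternatives (0.0527 to 0.180). Ccng2 and Cited2 fell as well (−2.35 and −1.78).

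Of the cytokine response genes followed throughout, Lta rose over time without IL-2 by 1.94 ± 0.12 (SE, adjusted p = 1.12e-05), Cish by 1.42 ± 0.31 (adjusted p = 0.00591) and Socs1 by 1.14 ± 0.26 (adjusted p = 0.00702). Socs1 was not called without the 4.5 h replicate 2 (0.88) or with array weights (0.95). The differences were 0.84 ± 0.20 for Socs3, 0.74 ± 0.21 for Pim1, 0.26 ± 0.13 for Socs2, 0.23 ± 0.22 for Bcl2 and −0.35 ± 0.27 for Myc, none of them called, and those of Socs2 and Bcl2 turned to −0.010 and −0.038 with ribosomal protein centring. Ccnd2 differed by −0.999 ± 0.14 (adjusted p = 6.14e-04), just short of 2-fold, and was called without the 30 min replicates 1 (−1.01), 2 (−1.02) or 3 (−1.02) or the 4.5 h replicate 2 (−1.10), and also with array weights, the mean over probe sets, median or ribosomal protein centring or a pseudocount of 1. Over the 24 lists 10 were called with 12 arrays, 5 up and 5 down, and 8 with 11 arrays, 5 up and 3 down, and 1 in each fit with an estimated correlation. The 16 lists not called with 11 arrays had adjusted p-values from 0.118 to 0.890. The scan day and the group cannot be told apart over time either, and the count of 1885 fell to 1130, 1111 and 1078 without the 4.5 h replicates 1, 3 and 4. The share of calls that were higher was 48.3% with 12 arrays and 49.2% with 11, against 37.6% with median centring of 12 arrays, and 13.9% and 19.7% with ribosomal protein centring, which moved the median of all probe sets by −0.27 and ended the calls of Socs1, Srsf3 and Rbm39.

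**Figure D3:**
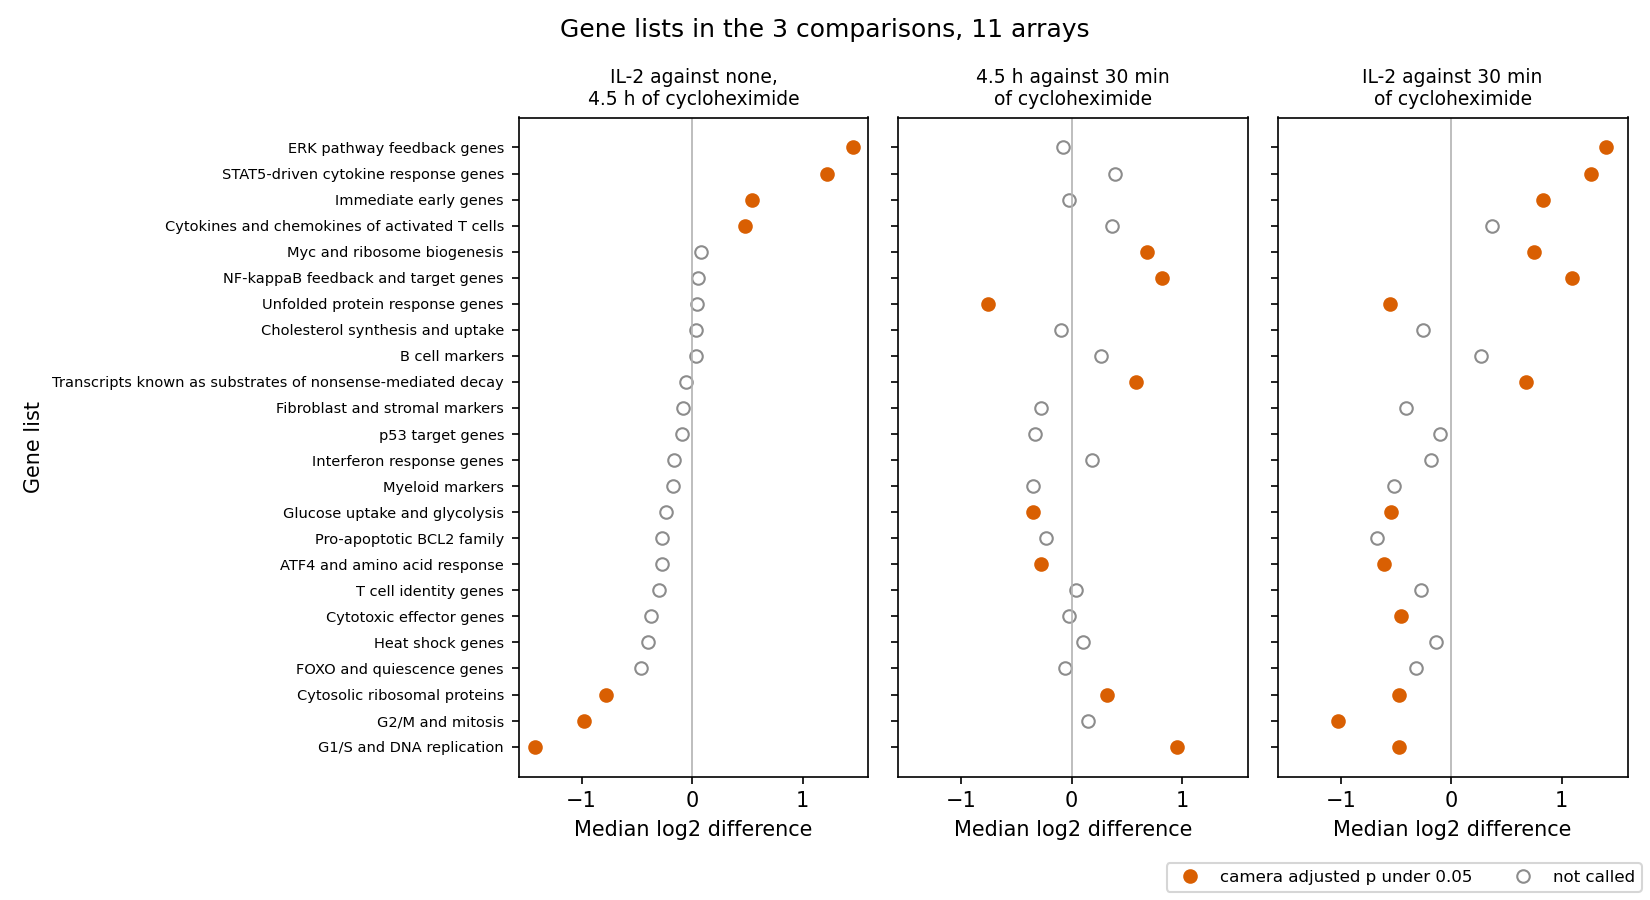
Median log2 difference of each gene list in the 3 comparisons with 11 arrays, where filled points had a camera adjusted p under 0.05. STAT5-driven genes stood at 1.22 with IL-2 at matched time and 1.27 against 30 min, and G1/S genes at −1.43 with IL-2 at matched time and 0.95 over time without it.

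IL-2 for 4 h was also set against the 30 min group, the state in which IL-2 was added, a comparison that mixes the cytokine with 4 h of time. With 11 arrays camera called 6 lists up, among them those of STAT5-driven, ribosome biogenesis and NF-kappaB genes, and 7 down, among them those of ATF4, unfolded protein response and mitosis genes. Of these 13 the ribosome biogenesis list alone held with an estimated correlation. Ppargc1a, a coactivator of mitochondrial gene expression, rose to 11990 ± 4578 (SD, n = 3) from 422 ± 293 (SD, n = 4), by 4.97 ± 0.50 on the log2 scale (SE, adjusted p = 1.02e-04). Lta rose to 8281 ± 825 (SD, n = 3) from 413 ± 17.9 (SD, n = 4), by 4.27 ± 0.13 (adjusted p = 1.40e-07). With 12 arrays 931 probe sets were called, 450 higher and 481 lower, representing 272 and 223 genes. Without the library labelled IL-2 plus cycloheximide replicate 3 there were 2851, 1701 higher and 1150 lower, representing 880 and 571 genes, and 827 of the 931 (88.8%) were called in the same direction in both with 0 opposite.

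Fos, Tube1, a tubulin, and Etv5, an ERK-induced transcription factor, rose by 4.55 ± 0.57, 4.34 ± 0.29 and 4.19 ± 0.37 (SE, adjusted p = 3.51e-04, 1.22e-05 and 4.30e-05). The largest falls were in Ankrd37 (−5.03), Chac1 (−4.27), Mxd4 (−3.61), Ccng2 (−3.5) and Zbtb42 (−3.28, all 5 with adjusted p from 3.39e-07 to 4.09e-04). For these genes all 3 IL-2 arrays lay on one side of all 4 arrays at 30 min, as the rule for naming them required. Of 20 STAT5-driven genes 10 rose and 0 fell, or 11 and 0 adjusted over the list alone (median 1.27, adjusted p = 8.85e-05, and adjusted p = 0.253 with an estimated correlation). Cish, Socs1, Socs3 and Socs2 rose by 3.49 ± 0.33, 3.45 ± 0.28, 2.57 ± 0.22 and 1.39 ± 0.14. Pim1 rose by 1.15 ± 0.23 and was not called without IL-2 plus cycloheximide replicate 4 (0.95) or with array weights (0.96). Il2ra differed by 0.34 ± 0.19 (adjusted p = 0.232) and Ccnd2 by −0.59 ± 0.16 (adjusted p = 0.02), short of 2-fold.

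Of 40 Myc and ribosome biogenesis genes 14 rose and 0 fell by either adjustment (median 0.75, adjusted p = 3.82e-10), and the call held with an estimated correlation (adjusted p = 0.0203). Myc rose by 2.99 ± 0.29 (SE), and Rrp1b, Wdr43 and Noc3l, which act in ribosome assembly, by 2.26 ± 0.16, 1.46 ± 0.14 and 1.39 ± 0.12. With all 12 arrays 13 of 40 rose (median 0.95, adjusted p = 5.97e-15, and adjusted p = 0.00404 with an estimated correlation). Of 17 NF-kappaB genes 9 rose and 1 fell by either adjustment (median 1.09, adjusted p = 7.83e-06, and adjusted p = 0.157 with an estimated correlation), with Bcl3 at 2.66 ± 0.18, Rel at 2.61 ± 0.28 and the adhesion molecule Icam1 at 1.35 ± 0.14. Of 34 immediate early genes 16 rose and 2 fell, or 16 and 3 adjusted over the list alone (median 0.83, adjusted p = 6.26e-05, and adjusted p = 0.157 with an estimated correlation), with Egr1 at 3.74 ± 0.30 and Gadd45b at 2.48 ± 0.13. Of 18 ERK feedback genes 9 rose and 0 fell, or 10 and 0 adjusted over the list alone (median 1.41, adjusted p = 3.62e-05, and adjusted p = 0.157 with an estimated correlation), with Dusp4 at 3.73 ± 0.18 and Spred1 at 2.63 ± 0.17. With all 12 arrays 7 of the 18 rose (median 1.24, adjusted p = 4.64e-08, and adjusted p = 0.0109 with an estimated correlation). Of 26 decay substrates 6 rose and 0 fell, or 7 and 0 adjusted over the list alone (median 0.67, adjusted p = 3.74e-05, and adjusted p = 0.157 with an estimated correlation). Ifng rose by 3.41 ± 0.35, Bcl2 by 1.86 ± 0.23, Bcl2l1 by 1.80 ± 0.23 and the pro-apoptotic Pmaip1 by 1.49 ± 0.23, while Bmf fell by 2.32.

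Of 27 G2/M and mitosis genes 15 fell and 0 rose, or 16 and 0 adjusted over the list alone (median −1.03, adjusted p = 5.38e-07, and adjusted p = 0.368 with an estimated correlation). Ccnb2 fell by 1.21 and Cdk1, the mitotic kinase, fell by 1.004, and Cdk1 was not called without IL-2 plus cycloheximide replicate 4 (−0.83) or the 30 min replicates 1 (−0.95) or 2 (−0.95), with array weights (−0.95) or with a pseudocount of 64 (−0.92). Of 34 G1/S genes 5 fell and 3 rose, or 6 and 3 adjusted over the list alone (median −0.47, adjusted p = 0.0150, and adjusted p = 0.246 with an estimated correlation), with Cdt1 lower by a log2 difference of −1.57. Of 32 ATF4 and amino acid response genes 7 fell and 2 rose by either adjustment (median −0.61, adjusted p = 5.64e-05, and adjusted p = 0.211 with an estimated correlation). Of 22 unfolded protein response genes 4 fell and 1 rose by either adjustment (median −0.55, adjusted p = 7.83e-04, and adjusted p = 0.231 with an estimated correlation). Of 19 glucose genes 2 fell and 1 rose by either adjustment (median −0.54, adjusted p = 0.00106, and adjusted p = 0.157 with an estimated correlation). The 44 ribosomal protein genes, 1 of them called lower, had a median of −0.47 (adjusted p = 3.17e-05, and adjusted p = 0.559 with an estimated correlation), and −0.04 with quantile normalization (adjusted p = 0.513). The 19 cytotoxic genes, 0 of them called, had a median of −0.45 (adjusted p = 0.00856, and adjusted p = 0.559 with an estimated correlation), which was −0.01 with quantile normalization (adjusted p = 0.632) and turned to 0.0032 with ribosomal protein centring. With the library labelled IL-2 plus cycloheximide replicate 3 the medians of the cytotoxic and T cell lists were −2.50 (adjusted p = 0.00941) and −2.13 (adjusted p = 0.0139), each with an adjusted p of 0.752 with an estimated correlation. The T cell list was not called without it (−0.28). Over the 24 lists 13 were called in each fit, 5 up and 8 down with 12 arrays and 6 up and 7 down with 11, of which 2 and 1 were called with an estimated correlation. With 12 arrays the STAT5, G1/S, ATF4 and glucose lists were not called (medians 0.78, 0.017, −0.18 and −0.30, adjusted p = 0.0728, 0.920, 0.506 and 0.0922). The STAT5 list was then called with median centring (0.0411) or no filter (0.0491), and the glucose list with the mean over probe sets (0.0489). Within the first scan day all 4 were called (8.67e-05, 0.00881, 2.28e-04 and 2.39e-04). The pro-apoptotic, cholesterol and FOXO lists were called down with 12 arrays and not with 11 (12-array medians −0.53, −0.42 and −0.43, adjusted p = 0.0236, 0.0289 and 0.00985, and 0.227, 0.711 and 0.101 as adjusted p with an estimated correlation). Of these the cholesterol call was lost without the 30 min replicate 1 (0.0754) or with a 60th percentile filter (0.0592), and the pro-apoptotic call without cross-hybridizing probe sets (0.0652). Neither was called within the first scan day (0.776 and 0.153), which does not hold the library labelled IL-2 plus cycloheximide replicate 3. The FOXO list kept its call within that day. The 11 lists not called with 11 arrays had adjusted p-values from 0.0527 to 0.892.

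Bbc3 fell by 1.16 (adjusted p = 0.0265) against 30 min, but was not called without IL-2 plus cycloheximide replicate 4 (−0.78, adjusted p = 0.101) or the 30 min replicate 1 (−1.01, adjusted p = 0.0658), with no filter (adjusted p = 0.0540) or within the first scan day (−1.20, adjusted p = 0.0773). Here the groups shared scan days. The scan day as a block was fitted only to the arrays of these groups, with the library labelled IL-2 plus cycloheximide replicate 3 among them. It gave 334 calls, more than the same arrays gave without the block. The first day alone, with 3 arrays in each group, gave 2518, 1515 higher and 1003 lower. Of the 2851 calls 2255 (79.1%) were made in the same direction within the first day and 0 in the opposite one. Called or not, 36 of 37 named genes and 13 of 13 lists stayed on the same side of the threshold, the exception being Bbc3. Of the arrays of these groups in the 11-array fit, the first day left out only the 30 min replicate 3. Most of this overlap was therefore given in advance, and it is no independent check of the scan day. The count of 931 fell to 557, 575 and 618 without the 30 min replicates 1 and 2 and IL-2 plus cycloheximide replicate 4. The share of calls that were higher was 48.3% with 12 arrays and 59.7% with 11, against 48.8% with median centring of the 11, and 87.3% and 93.0% with ribosomal protein centring, which moved the median of all probe sets by 0.34 and 0.46 and ended the calls of Ccnb2, Cdk1 and Bbc3. In the 3 comparisons together, 50 of the calls of named genes were not made by limma's treat, which tests whether a change exceeds 2-fold.

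Many probe sets higher with IL-2 at matched time were not called against the 30 min arrays. Of the 1783 probe sets higher at matched time in the 11-array fit, 606 (34.0%) were also higher than at 30 min, 20 (1.12%) were lower and 1157 (64.9%) were not called against 30 min. Among the last, Il2ra, Csn2 and Cd28 rose with IL-2 at matched time and fell over time without it. Il2ra stood at 4823 ± 1169 (SD, n = 4) at 30 min, 1370 ± 154 (SD, n = 4) at 4.5 h and 5994 ± 280 (SD, n = 3) with IL-2. Of the 1489 lower probe sets 357 were also lower than at 30 min, 11 were higher and 1121 were not called. Independent lists of these sizes, which leave out the shared arrays, would share 112 higher and 63.4 lower probe sets. With no effects in the data, 20 simulations of unchanged groups gave 0 of each. In the 12-array fit 85 and 111, together 196, were shared, and with the IL-2 group split between the comparisons 35 to 53 and 46 to 75 were. Each split put the library labelled IL-2 plus cycloheximide replicate 3 among the 2 IL-2 arrays of one comparison. With it at matched time 140 to 239 probe sets were called higher there, and with it against 30 min 1559 to 1612 were. Part of the overlap may come from the shared IL-2 arrays.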

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

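Of the tests given here, those for a failed array, a mixture and an exchange on the library labelled IL-2 plus cycloheximide replicate 3, the scan-day test and the histone test were chosen only after the result was seen. In each group of 4 arrays a value was marked when the gap between the most extreme array and its nearest neighbour exceeded 0.829 of the group's range, which chance does in about 1 in 20 groups. Among array measures 10 of 39 groups were marked, among list means of the 30 min and 4.5 h groups 4 of 52, and among named genes of those groups 19 of 196.

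The library labelled IL-2 plus cycloheximide replicate 3 stood apart in its group for the percent of probe sets over 500 (0.869 of the range), its median correlation with the group (0.987), its highest correlation with any array (0.992), and the mean log2 of T cell genes (0.982) and of cytotoxic genes (0.981). It also stood apart for 10 of 26 list means and 54 of 98 named genes. On it 968 probe sets with a signal over 500 were over 10-fold higher than on every other array, and 0 were on any other array. A further 578 probe sets, over 500 on every other array, were over 10-fold lower on it. That lower direction was not counted for the other arrays.

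A failed array is argued against by 22.1% of its probe sets lying above 500, and a mixture with CTLL-2 RNA by a median of 0.202% of the level of the other IL-2 arrays over 26 bright T cell and cytotoxic genes, 25 of which were under 5%, the exception being Lamp1 at 172%, a lysosomal gene of most cells. An exchange within the series is argued against by 0 other arrays lacking T cell genes. RNA of skeletal muscle type from outside the series is a candidate explanation, since 69.0% of 29 muscle markers (20, exact 95% interval 49.2 to 84.7) were over 10-fold above every other array, among them Myh3, Ttn and Tnnc2. Against it Ckm, a muscle gene outside that list, was at 1690, under the 4563 of another array. That list was chosen after Myod1 and other muscle genes had been seen. Its members Myh3, Tnnc2, Cdh15 and Chrnd were among the 11 muscle genes read first. The share and its interval are therefore not a test on unread genes alone. Adipose markers gave 7.69% (Lpl), fibroblast markers 18.2% (Col3a1 and Fn1) and liver, neuron, epithelium, endothelium, B cell, myeloid and erythroid markers 0%. No biological explanation within the design was tested.

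In the 11-array fit 1020 probe sets, 31.2% of the 3272 called with IL-2 at matched time, were also called in the opposite direction over time without IL-2 and had an adjusted p of 0.05 or more against 30 min, so that the 4.5 h arrays stood apart from both other groups. They include Il2ra, Csn2, Cd28, Rnf207, Rpl27a and the replication genes Mcm3, Mcm4 and Gins2, with 427 higher and 593 lower at 4.5 h. A biological reading is that IL-2 held these transcripts near their starting level, and a technical one is a difference in labelling or in the day of the 4.5 h arrays. Other probe sets of the same genes moved along in 39.9% (273 of 685, exact 95% interval 36.2 to 43.6), between 8.03% for random probe sets and 61.4% for probe sets that differed in the IL-2 arrays alone (Fisher's exact test of 39.9% against 61.4%, p = 3.84e-13). The interval and p-value count probe sets as independent, which those of 1 gene on the same arrays are not, so both overstate the precision. The readings cannot be told apart, and 0 of the 4.5 h arrays shared a scan day with another group. For Actb, chosen after its values were seen, 1 probe set went from 328 to 3070 over time while a brighter one stood at 48975 and 51469.

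On the 4.5 h arrays the poly-A spikes, added to the RNA as controls, were 6.91-fold higher than on the other 8 (exact permutation test over 495 splits, two-sided p = 0.00202) and 18S ribosomal RNA was 2.36-fold higher (p = 0.0101), while hybridization spikes differed by 1.21-fold (p = 0.457). The first p is the lowest that 495 splits can give. The 4.5 h arrays shared 1 scan day, so these p-values cannot tell treatment from that day. The other 8 include the library labelled IL-2 plus cycloheximide replicate 3, whose 18S mean log2 of 8.88 lay within the 4.5 h range of 8.37 to 9.62. Replication-dependent histone transcripts, which lack poly-A tails, were higher at 4.5 h than at 30 min, and more RNA without such tails in the labelled target is a possible explanation. The smaller median difference over 30 histone probe sets between the 4.5 h arrays and the other groups was 0.467, short of the 0.5 that explanation would need and above the 0.2 that would exclude it. The median was 1.02 over time (15 higher, 1 lower, camera p = 0.0383 with an estimated correlation), 0.72 for IL-2 against 30 min (10 higher, 0 lower, camera p = 0.0668 with an estimated correlation) and −0.47 with IL-2 at matched time. The last turned to 0.26 with ribosomal protein centring. The comparison of IL-2 with 30 min holds no 4.5 h array, so the labelling of the 4.5 h arrays cannot account for its median. For the rise at 4.5 h itself, the labelling and a biological rise cannot be told apart.

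The 4.5 h replicate 2 stood apart for its median correlation with the group (0.978), its highest correlation with any array (0.982), the 3′ to 5′ difference of Gapdh (0.939), and the means of STAT5-driven genes (0.880), ribosomal protein genes (0.928) and fibroblast markers (0.934). It did so too for Bbc3 (0.930), Bcl2 (0.921), Bcl3 (0.923), Cish (0.830), Dkc1 (0.881), Jpt2 (0.843), Nfkbia (0.846), Osm (0.878), Rrs1 (0.836) and Socs2 (0.879), with a Cish signal of 4960 against 1551 to 1891 on the other 4.5 h arrays. The 30 min replicate 2 stood apart for its median correlation with the group (0.852), pro-apoptotic genes (0.901) and Stat2 (0.952), and IL-2 plus cycloheximide replicate 4 for the poly-A spikes (0.831). The 30 min replicate 1 stood apart for Bbc3 (0.903) and Jpt2 (0.866), replicate 3 for Polr1b (0.840) and replicate 4 for Ccnd2 (0.906), Dusp4 (0.935) and Gins2 (0.832), and the 4.5 h replicate 1 for Espn (0.857) and Igfals (0.864).

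Splits of the arrays into groups of the same sizes were counted as well, with the real split among the 35. Only 1 of 35 gave as many called probe sets as the real one in each comparison and fit, the fewest that can occur. With 35 splits no stronger statement is possible, and other splits mix the groups, which widens the spread and lowers their counts. The count cannot tell treatment from scan day where the 4.5 h arrays take part. With 12 and 11 arrays the highest other split gave 5 and 58 for IL-2 at matched time, 1 and 1 over time, and 3 and 274 for IL-2 against 30 min. For lists, adjusted here within 1 comparison rather than over 72 tests, as many were called in 34 and 7 of 35 splits with IL-2 at matched time (real 7 and 7, highest other 14 and 8), in 1 and 5 over time (10 and 8, highest other 9 and 9), and in 6 and 1 for IL-2 against 30 min (13 and 15, highest other 16 and 13). Chance is therefore not excluded for the number of lists called with IL-2 at matched time in either fit, over time with 11 arrays, or against 30 min with 12 arrays.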

How the results depend on the processing

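The fits without the library labelled IL-2 plus cycloheximide replicate 3 and within the first scan day were chosen only after the data were seen. Where no reason is given, the cause was not tested. Besides leaving out arrays, 2201 of the values of 142 gene results with 11 arrays kept direction and side of the threshold, 77 fell short of it, 11 passed it and 3 reversed, and of 36 list results 567 values kept both, 7 fell short, 3 passed and 12 reversed. With IL-2 at matched time quantile normalization turned the medians of cytotoxic, T cell and glucose lists to 0.10, 0.26 and 0.045, and ribosomal protein centring turned those to 0.35, 0.42 and 0.48, the FOXO list to 0.26, the pro-apoptotic list to 0.45 and the interferon list to 0.56. The cholesterol list turned to −0.039 with the mean over probe sets or without cross-hybridizing probe sets, and gave −0.015 to 0.069 leaving out arrays. Ribosomal centring also turned the cytotoxic list against 30 min to 0.0032 and, over time, Socs2 to −0.010 and Bcl2 to −0.038, and the mean over probe sets turned Rbm39 to −0.51. With 12 arrays the cytokine list at matched time (−0.0092) turned to 0.11 with quantile normalization, 0.056 with median and 0.60 with ribosomal centring, 0.066 with a pseudocount of 64, 0.43 with a 60th percentile filter and 0.49 with weights, and the ATF4 list to −0.18 with weights. Against 30 min ribosomal centring turned the ATF4 and glucose lists to 0.16 and 0.044, and the G1/S list (0.017) turned to −0.0024 with a pseudocount of 1, −0.45 with weights, −0.016 as a mean over probe sets and −0.55 within the first day. Leaving out arrays gave −0.38 to 0.48, −0.28 to 0.36 and −0.47 to 0.18 for the cytokine, ATF4 and G1/S lists. Ribosomal centring removes that list's own shift by construction, stricter thresholds lower a count and no fold threshold raises it by construction.

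For IL-2 at matched time (1196) ribosomal centring called 3113, array weights 3704, only the 2 groups compared 568, treat 9, an adjusted p under 0.01 354, the 11 arrays 3272, and leaving out each array 536 to 3272. With 11 arrays (3272) the counts were 8293 with ribosomal centring, 235 with treat, 7441 with no fold threshold and 2971 to 3184 leaving out arrays. Over time (1885) they were 3752 with weights, 3456 with 2 groups, 13 with treat, 676 under 0.01, 3570 with the 11 arrays and 1078 to 3570 leaving out arrays, and with 11 arrays (3570) 2247 with a pseudocount of 64, 238 with treat, 8486 with no fold threshold and 3317 to 3663. Against 30 min (931) they were 573 with ribosomal centring, 2841 with weights, 8 with treat and 308 under 0.01. Only the 2 groups compared gave 140, and those 2 groups with the scan day as a block gave 334. The first day gave 2518, and leaving out arrays 557 to 2851. With 11 arrays (2851) the counts were 292 with treat, 6321 with no fold threshold and 2560 to 3051 leaving out arrays. Shared calls (196) were 962 with weights, 41 with 2 groups, 2 with treat, 313 with no fold threshold, 54 under 0.01 and 106 to 963, and with 11 arrays (963) 2469 with ribosomal centring, 70 with treat, 2801 with no fold threshold and 880 to 995. Lists called at matched time (7) were 12 with ribosomal centring, 1 with an estimated correlation and 7 to 10 leaving out arrays, over time (10) 1 and 8 to 10, and against 30 min (13) 2, 6 with fry and 11 to 13. With 11 arrays they were 0 with an estimated correlation, 13 with fry and 7 to 8 at matched time, 1, 15 and 7 to 8 over time, and 1 and 13 to 14 against 30 min.

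With the replicate number as a block 943, 1683 and 678 probe sets and 9, 10 and 12 lists were called with 12 arrays, with 139 shared calls, and 3183, 3563 and 2846 probe sets and 7, 8 and 14 lists with 11, with 941 shared, and the block ended the calls of Slc2a1 at matched time (0.99) and Bbc3 against 30 min (adjusted p = 0.0523). The numbers were not taken to pair the arrays, since the labels name no shared batch. With 11 arrays, deviations of same-numbered IL-2 and 30 min arrays correlated at 0.09 to 0.215 (mean 0.143). Those of arrays with different numbers correlated at −0.191 to 0.165 (mean −0.048). Replicates 1, 2 and 4 of both groups were all scanned on the first day, so a shared scan day does not single out same-numbered arrays. A pairing of same-numbered arrays is not excluded. Splitting the shared IL-2 group was run only with 12 arrays. Signals near background limit the dim genes, whose differences shrink with the pseudocount.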

Other observations

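The hypoxia lists here were chosen only after falls of Ankrd37 and Slc2a1 had been seen, and the rule that the interval of the median must exclude a fall was set after its value was seen. Several genes induced by low oxygen were lower after 4.5 h of cycloheximide than after 30 min. In a list of 13 picked from their values 9 fell and 0 rose (median −1.30), so its p is not independent evidence. P4ha1, a collagen prolyl hydroxylase (−2.10), Ero1a, an oxidase of the endoplasmic reticulum (−1.5), Bnip3 (−1.25) and Ddit4, an inhibitor of mTOR signalling (−1.57), fell, while Pgk1, a glycolytic enzyme, differed by 0.02 and Ldha by −0.14, neither called.

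The hypothesis that hypoxia-inducible genes fell together was tested on 22 other such genes whose values had not been read. Their median was −0.0544, with an interval of −0.98 to 0.28 that covers at least 95% if genes are independent. Of them 3 fell (Vegfa, Mxi1 and Fam162a, at −1.13, −1.02 and −1.23) and 0 rose, with camera p = 0.218 and p = 0.322 with an estimated correlation. By the rule set beforehand, which used the median alone, this value argued against a shared fall. Only the rule on the interval, added later, left the question open. The interval takes in both no change and a fall, so under that added rule whether these genes fell together cannot be told from these arrays. The scan day of the 4.5 h arrays stays confounded with the comparison.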
